A study of Drosophila melanogaster with 35 samples.

How the data were processed

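The data came from fractionated individual-nucleotide crosslinking and immunoprecipitation (iCLIP) of CLAMP, a zinc-finger protein that binds GA-rich DNA and takes part in X chromosome dosage compensation in Drosophila. 35 libraries fall into 12 groups by 2 cell lines, 3 cell fractions and use or omission of the antibody. S2 is a male line and Kc a female line, and the fractions are chromatin, nucleoplasm and cytoplasm. 24 libraries are CLAMP precipitations, 4 in each line and fraction, and 11 are no-antibody controls, 2 in each line and fraction except 1 in Kc chromatin. Per the labels' protocols, cells were crosslinked with ultraviolet light of 254 nm, barcodes of 4 nt were used and libraries were amplified over 31 PCR cycles.

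Per the submitters' processing notes, the tools were UMI-tools, cutadapt 3.5, FastQC and STAR 2.5.2b-2, and the genome build was dm6. The peak caller and its threshold are not given in the sources used here. The authors deposited 1 peak list for a line and fraction, and 5 lists were analysed: S2 chromatin, Kc chromatin, S2 nucleoplasm, Kc nucleoplasm and Kc cytoplasm. A list for S2 cytoplasm was not analysed here. From the labels, all 4 CLAMP libraries of a group name its list except in Kc nucleoplasm, where 3 of 4 do. Of the no-antibody libraries, 1 of 2 names its list in S2 chromatin, S2 nucleoplasm and Kc nucleoplasm, 1 of 1 in Kc chromatin and 2 of 2 in Kc cytoplasm. Which libraries entered a list is not given in the sources used here. The label of a no-antibody library of Kc chromatin names the Kc nucleoplasm list as well as its own. The deposited lists hold peak start and end coordinates, a strand and a score. The deposited score was 0 in every peak, so it carried no information and no peak was ranked or filtered by it. The lists give no read counts, so the depth of each library and of each peak is unknown.

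Each peak was placed on the gene annotation of Ensembl release 115 with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Coordinates are 1-based on dm6. A peak took the class found at its midpoint on its own strand, in this order: exon of a non-coding RNA under 500 nt, rRNA exon, 5' UTR, CDS, 3' UTR, other non-coding RNA exon, transposable element, intron, antisense to a gene, intergenic. The transposable element class was added after the annotation was examined, and transposable elements were not counted as target genes. Peaks on scaffolds that the annotation does not cover formed an 11th class. The scaffold that holds rDNA units carries another name in the annotation, and the match was inferred. It was checked by the share of plus-strand peaks that fell in annotated rRNA genes, which was 98.4% in S2 chromatin, 92.6% in Kc chromatin, 98.7% in S2 nucleoplasm, 96.2% in Kc nucleoplasm and 75% (3 of 4 peaks) in Kc cytoplasm. The rDNA block of the X chromosome was taken as X 23200802 to 23538283.

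A target gene had at least 1 peak on its strand. Each peak was given to 1 gene, with exonic overlap before intronic overlap and small non-coding RNAs before other genes. Shares of peaks were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 44 tests of classes and over 57 tests of gene lists. Differences between lines in the step from nucleoplasm to chromatin were tested with Zelen's exact test of equal odds ratios. Odds ratios had a continuity correction. Overlaps of target genes were compared with a one-sided Fisher's exact test over 18358 annotated genes, which overstates the excess because the genes expressed in these cells were not known. Shared positions were tested by placing the peaks of a list 1000 times at random within the same gene and the same exon or intron class, and the smallest p this can give is 0.0010. Intervals are Wilson 95% intervals, or Woolf intervals for odds ratios. All intervals and tests treat peaks or genes as independent and cover counting error only. Each line and fraction has 1 list, so no value has a spread between replicates, and p-values compare these lists, not repeated experiments. No control peak list was used here, so no background was set beside the values.

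The gene lists, the comparisons between lists and the rule for named genes were fixed before the data were examined. Zelen's test and the tests on rDNA dilution, peak width, shared coding targets, 18S offsets, transposable element families and snoRNA box classes were chosen after results were seen. With no varying score, genes were ranked by number of peaks. The rule took the 10 genes with most peaks in each list, the 10 with most peaks in both lists of an S2 and Kc comparison, the 6 with most peaks in each line and none in the other, every dosage compensation and sex determination gene with a peak, and up to 4 genes of each other gene list. It named 81 genes. The 18 gene lists were dosage compensation, sex determination, spliceosomal snRNAs, other structural small RNAs, snoRNAs, ribosomal RNAs, tRNAs, mitochondrial genome, ribosomal proteins, replication-dependent histones, heat shock, SR and hnRNP splicing regulators, core spliceosome proteins, translation factors, GAGA-site, insulator and Polycomb proteins, cytoskeleton, hemocyte markers, and markers of other cell types.

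The procedures were tested on simulated data. Of 400 simulated peaks per list, 98.2% were returned to their own gene for S2 chromatin, 99% for Kc chromatin, 97.2% for S2 nucleoplasm and 99% for Kc nucleoplasm. With equal shares of 10%, the class test passed 0.05 in 5.2% of 500 simulations for S2 against Kc chromatin and in 5.4% for the nucleoplasm lists. With shares of 5% against 15%, the class test passed in 100% and 99.8%. The placement test, run on 30 simulated genes, passed in 3% of 100 simulations of unrelated sites and in 100% where a part of the sites was shared. These were long protein-coding genes with a peak each. Most peaks in the shared genes lay in rRNA genes and small RNAs, so these rates do not cover them. The test of distance to splice junctions, run on 200 simulated peaks, passed in 6% of random and 100% of enriched simulations. Zelen's test passed in 3.6% of 500 simulations with equal odds ratios and in 92.8% with shares of 15% against 5% in S2 chromatin and nucleoplasm alone. The simulations of the class test and of Zelen's test drew independent counts. Their rates do not cover peaks that recur in copies of a gene.

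Alternatives merged peaks within 50 nt, ignored strand, assigned every overlapped gene, classified the whole peak, counted peaks or positions in place of genes, kept protein-coding genes alone, raised the overlap required, or placed peaks anywhere in the gene. Others, chosen after seeing the data, left out rDNA and rRNA genes, counted copies of an RNA once, left out genes under 500 nt, left out protein-coding genes, or kept peaks of at least 30 nt. The planned search for sequence motifs was not run because no genome sequence was used here, and a stricter score threshold was not possible.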

Results

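The peak lists are the authors' calls from CLAMP iCLIP of S2 cells, a male Drosophila line, and Kc cells, a female line. They cover chromatin and nucleoplasm of both lines and the cytoplasm of Kc cells. No background was set beside them here, so a peak is not shown to be a CLAMP contact. The series asks how RNA contacts of this X chromosome dosage compensation protein differ between the sexes and fractions. The 5 lists hold 3235 peaks. Each list is named in the labels of 4 CLAMP libraries, or 3 for Kc nucleoplasm, and of at least 1 no-antibody library, and which libraries entered it is not given in the sources used here. S2 chromatin had 1416 peaks with a median width of 39 nt, and Kc chromatin had 874 with a median width of 58 nt. S2 nucleoplasm had 391 peaks (median 52 nt), Kc nucleoplasm 546 (median 58.5 nt) and Kc cytoplasm 8 (median 85 nt). Read depth is unknown and the lists have no replicates, so numbers of peaks are described without a test.

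Messenger RNAs, small RNAs and ribosomal RNAs all carried peaks, in proportions that differed between lists. S2 chromatin peaks fell in 634 target genes, of which 418 were protein-coding, 174 small non-coding RNAs and 34 rRNA genes. Kc chromatin peaks fell in 197 target genes, with 72 protein-coding, 87 small RNA and 35 rRNA genes. S2 nucleoplasm had 56 target genes (10 protein-coding, 25 small RNA, 20 rRNA) and Kc nucleoplasm 123 (59 protein-coding, 34 small RNA, 28 rRNA). Copies of an RNA were counted as separate genes, so the small RNA numbers are not numbers of distinct RNAs. Of 10 tRNA:Asn-GTT genes, 10 had a peak in S2 chromatin and 4 in Kc chromatin. Of 8 tRNA:Phe-GAA genes, 8 and 3 did. Whether single sites were called in several copies was not tested for small RNAs. Peaks on autosomes and on the X outside its rDNA block made up 56.0% of the S2 chromatin list and 24.9% of the Kc chromatin list (Fisher's exact p = 3.05e-49). In nucleoplasm the order was the opposite, 10.2% in S2 and 18.5% in Kc (Fisher's exact p = 4.23e-04).

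Between the chromatin fractions of the lines, protein-coding transcripts took a larger share of peaks in S2 and rRNA a larger share in Kc. CDS peaks made up 15.5% of S2 chromatin peaks (13.7 to 17.5%; 220 of 1416) and 2.06% of Kc chromatin peaks (1.31 to 3.23%; 18 of 874), an odds ratio of 8.53 (adjusted exact p = 5.00e-28). The 3' UTR share was 11.3% (9.75 to 13.1%) in S2 and 3.20% (2.23 to 4.59%) in Kc (odds ratio 3.79, adjusted exact p = 4.31e-12). The 5' UTR share was 2.47% in S2 and 0.229% in Kc (adjusted exact p = 3.46e-05). Exons of rRNA held 18.1% of S2 chromatin peaks (16.2 to 20.2%; 257 of 1416) and 32.4% of Kc chromatin peaks (29.4 to 35.6%; 283 of 874), with an adjusted exact p of 1.56e-13. The rRNA peaks were similar in number, so their larger share in Kc came with fewer peaks of other classes there. Without rDNA and rRNA genes, the few remaining rRNA exon peaks gave an odds ratio of 0.647 (adjusted exact p = 0.332). The intron shares, 4.03% and 3.09%, did not differ by the test (adjusted exact p = 0.425) but did with strand ignored (odds ratio 1.70, adjusted exact p = 0.0313). Nor was a difference found in small non-coding RNA exons (13.1% and 11%, adjusted exact p = 0.201). Among peaks of at least 30 nt the small RNA odds ratio was 1.54 (adjusted exact p = 0.00636). Scaffolds without annotation held 15.7% and 27.7% (222 and 242 peaks; adjusted exact p = 5.13e-11). Intergenic peaks were 10.3% and 14.5% (adjusted exact p = 0.00736), with the odds ratio turning from 0.676 to 1.63 without rDNA (adjusted exact p = 0.177). Peaks antisense to a gene were 4.03% and 2.17% (odds ratio 1.86, adjusted exact p = 0.0310), a call lost under 3 of 4 alternatives that kept the class. The odds ratios were then 1.52 with peaks merged, 1.76 by class over the whole peak and 1.92 at 30 nt or more.

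**Figure D1:**
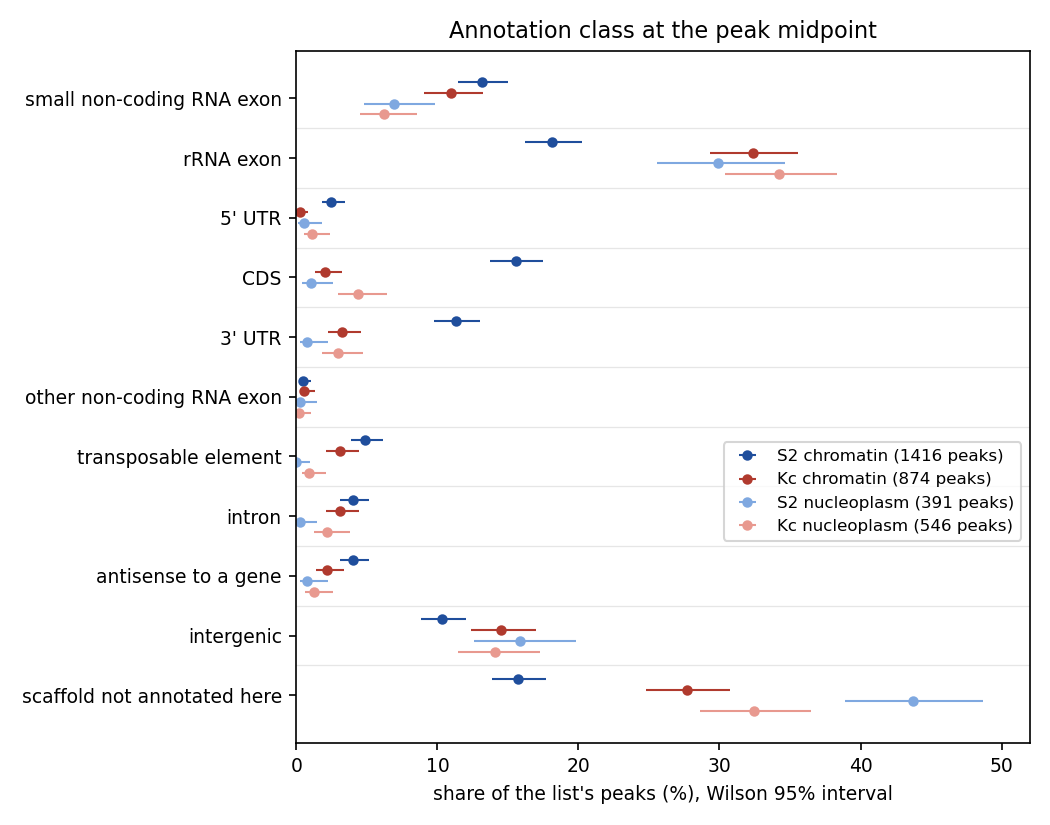
Share of each list's peaks (x axis, percent) by annotation class at the peak midpoint (y axis) for 4 lists. Points are shares and bars Wilson 95% intervals, and S2 chromatin stands apart in CDS (15.5%) and 3' UTR (11.3%).

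Transcripts of pAbp, which encodes the poly(A)-binding protein, had 7 peaks in S2 chromatin and 1 in Kc chromatin. Of the S2 peaks, 6 lay in the 3' UTR, and the peak at 2R 18145844 to 18145870 overlapped the Kc peak at 2R 18145820 to 18145864. For sqd, which encodes an hnRNP protein, Kc chromatin had 5 peaks, all in the 3' UTR between 3R 13637806 and 13640624, and S2 chromatin 1, at 3R 13640125 to 13640147. Of the 7 pAbp peaks in S2, 1 was at least 30 nt wide, and the S2 peak in sqd was 23 nt wide. Among genes with peaks in S2 chromatin and none in Kc chromatin, 7SLRNA:CR32864, an RNA of the signal recognition particle, had 4, and the laminin genes LanB1 and LanB2, Bsg, Df31 and lncRNA:CR34335 had 3 each. Of the LanB2 peaks, 0 were at least 30 nt wide. In the opposite direction, the transcription factor gene lola had 2 Kc chromatin peaks, both intronic, at 2R 10518493 to 10518524 and 10539273 to 10539309. The snoRNAs Or-aca3, Psi18S-1295, Psi18S-1854a and Psi28S-1135e also had 2 Kc chromatin peaks each and 0 in S2 chromatin.

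**Figure D2:**
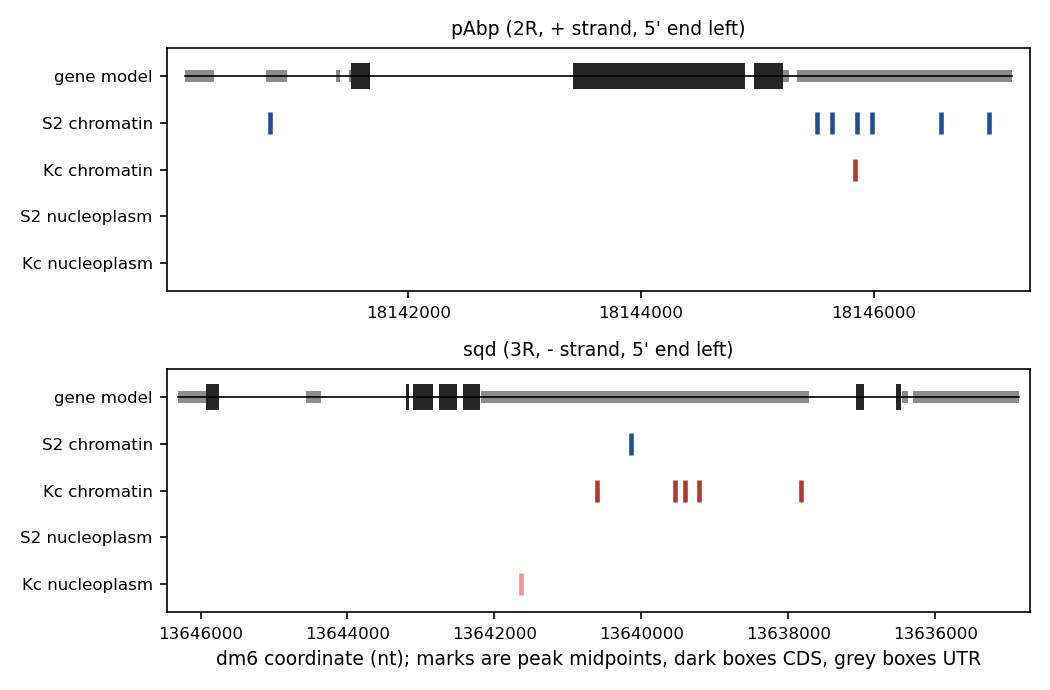
Peak midpoints (marks) of 4 lists along pAbp and sqd, with dm6 coordinates in nt on the x axis, the 5' end at the left, CDS as dark boxes and UTRs as grey boxes. S2 chromatin had 7 peaks in pAbp against 1 in Kc chromatin, and Kc chromatin 5 in sqd against 1 in S2 chromatin.

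Small nucleolar RNAs, many of which guide modification of rRNA, were found in similar numbers in both chromatin lists but were a larger part of the smaller Kc set of target genes. They were 41 of 197 genes (20.8%) in Kc and 36 of 634 (5.68%) in S2 (adjusted exact p = 9.93e-08; 1.39e-08 adjusted over the list alone). With protein-coding genes left out, the difference shrank from an odds ratio of 0.230 to 0.412 (adjusted exact p = 0.00691), beside more tRNA genes in S2. Most of these snoRNA genes differed between the lists where names give the box class. Of H/ACA RNAs, 22 were in Kc, 6 in S2 and 2 in both, and of C/D RNAs 14, 18 and 5. Examples with peaks in both lists were U3:9B on the X (2 peaks in each) and U3:54Ab on 2R (1 in each). Ribosomal RNA genes were 33 of the Kc target genes (16.8%) and 32 of the S2 target genes (5.05%), an odds ratio of 0.265 (adjusted exact p = 1.73e-05; 1.82e-06 adjusted over the list alone). The rRNA call was lost with copies counted once (odds ratio 0.274, adjusted exact p = 0.236) and with protein-coding genes left out (0.486, adjusted exact p = 0.0549). Transfer RNA genes were 113 of the S2 and 36 of the Kc target genes, 17.8% and 18.3% (adjusted exact p = 1). The tRNA odds ratio of 0.963 depended on the setting, with 0.494 for copies counted once (adjusted exact p = 0.191; 0.0402 adjusted over the list alone) and 2.69, higher in S2, with protein-coding genes left out (adjusted exact p = 7.02e-04). Spliceosomal snRNA genes were 18 and 7, such as U5:63BC with 2 and 1 peaks, and other structural small RNAs 4 and 3 (adjusted exact p = 1 for each).

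The remaining gene lists did not differ between the chromatin lists as shares of target genes, each with an adjusted exact p of 1. Several had too few members with a peak for the test to detect a difference. Ribosomal protein genes numbered 22 in S2, with 2 peaks each in RpL41, RpL17, RpL3 and RpL4 (24 nt wide in RpL4), and 4 in Kc. With every overlapped gene counted they numbered 22 and 14 (odds ratio 0.513 in place of 1.58, adjusted exact p = 0.573). Of the 24 translation factor genes in the list, 6 had peaks in S2, among them eEF1alpha1 with 2 CDS peaks, and 1 in Kc, which was pAbp. The list was not complete: eIF3c, which it did not hold, had 1 peak in each chromatin list. Splicing regulators numbered 5 in S2, among them Hrb98DE and Hrb27C, and 4 in Kc, with sqd and ps in both. Hemocyte markers, genes of the blood cell type that both lines resemble, numbered 6 in S2, including LanA, LanB1, LanB2 and the collagen gene vkg, and 0 in Kc. Heat shock genes numbered 3 (Hsc70-3, Hsc70-4 and Hsp83) and 0, and cytoskeletal genes 5 and 2, with Act5C and kst in both. GAGA-site, insulator and Polycomb genes numbered 1 (Cp190) and 0. Genes of the mitochondrial genome, mostly rRNAs and tRNAs, numbered 22 in S2 (7 of them coding) and 10 in Kc (0 coding). Replication-dependent histones, core spliceosome proteins and markers of other cell types had 0 members in any list.

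No difference in the X share of target genes was detected between the male and the female line. In chromatin, 110 of 596 S2 target genes on the X or autosomes were X-linked (18.5%, 15.5 to 21.8%) against 32 of 173 in Kc (18.5%, 13.4 to 24.9%; Fisher's exact p = 1). In nucleoplasm the shares were 33.3% (21.4 to 47.9%; 15 of 45) and 26.9% (19.3 to 36.2%; 28 of 104), with a Fisher's exact p of 0.437. Without rDNA and rRNA genes the odds ratio rose from 0.989 to 1.57 in chromatin (Fisher's exact p = 0.103) and fell from 1.36 to 1.05 in nucleoplasm (Fisher's exact p = 1). For protein-coding target genes they were 18.3% in S2 chromatin and 12.5% in Kc chromatin (Fisher's exact p = 0.311), beside 15.7% of annotated protein-coding genes. Counted as peaks, the odds ratio for the X was 0.420 (Fisher's exact p = 1.73e-09), but outside the X rDNA block 15.5% of S2 and 13.8% of Kc chromatin peaks were on the X (Fisher's exact p = 0.594).

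Of the 10 annotated dosage compensation genes, roX2 and Unr had a peak, both in S2 chromatin. The peak in roX2, an RNA of the male-specific lethal complex, lay at X 11580083 to 11580105 and was 23 nt wide. Unr, which encodes a repressor of msl-2 translation, had a 3' UTR peak at 3L 8432474 to 8432512. Among sex determination genes, Sxl, the female-specific switch gene, had an intronic peak in Kc nucleoplasm at X 7096195 to 7096242. The gene fru had a 3' UTR peak in S2 chromatin at 3R 18415871 to 18415897 and an intronic peak in Kc nucleoplasm at 3R 18446533 to 18446560. These counts were too small for the test to detect a difference between the lines, so no conclusion is drawn from it (Fisher's exact, adjusted p = 1 for both gene lists in chromatin and for sex determination in nucleoplasm). The peaks in roX2 and fru were under 30 nt wide.

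In nucleoplasm, with peaks of all widths, CDS and introns took a smaller share of peaks in S2 than in Kc, the reverse of the order for CDS in chromatin. CDS peaks were 1.02% (0.399 to 2.60%; 4 of 391) in S2 and 4.40% (2.97 to 6.46%; 24 of 546) in Kc (adjusted exact p = 0.00736). Intron peaks were 0.256% in S2 and 2.2% in Kc (adjusted exact p = 0.0236). Both calls were lost among peaks of at least 30 nt, with odds ratios of 0.273 for CDS (adjusted exact p = 0.0949) and 0.106 for introns (adjusted exact p = 0.0832). The 3' UTR shares were 0.767% and 2.93% (adjusted exact p = 0.0578), and the odds ratio passed the test when rDNA was left out (0.273, adjusted exact p = 0.0397), with peaks merged (0.265, adjusted exact p = 0.0352) and at 30 nt or more (0.0543, adjusted exact p = 0.00594). Scaffolds without annotation held 43.7% of S2 and 32.4% of Kc nucleoplasm peaks (adjusted exact p = 0.00171), and rRNA exons 29.9% and 34.2% (adjusted exact p = 0.262).

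No gene list differed between the nucleoplasm lists after adjustment. Spliceosomal snRNA genes were 7 of 56 S2 and 4 of 123 Kc target genes (adjusted exact p = 0.355), with U1:21D, U1:95Ca and U2:34ABa in both. Ribosomal RNA genes were 19 and 26 (adjusted exact p = 0.762), tRNA genes 15 and 21 (adjusted exact p = 0.911), and snoRNA genes 3 and 8 (adjusted exact p = 1). Mitochondrial genes were 1 and 6, and cytoskeletal genes 0 and 2. Ribosomal proteins, heat shock genes, splicing regulators, translation factors, GAGA-site, insulator and Polycomb genes and hemocyte markers had 0 in S2 and 1 each in Kc, among them RpL41, lncRNA:Hsromega, sqd and pho (adjusted exact p = 1 for each). Counts this small could not have passed the test. The S2 nucleoplasm list named few coding genes, such as CG1317, CG31224, CG31523 and CG3847, with 1 peak each.

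Within S2 cells, CDS, 3' UTRs and introns took a larger share of peaks in chromatin than in nucleoplasm. CDS peaks were 15.5% of the chromatin and 1.02% of the nucleoplasm list (odds ratio 15.9, adjusted exact p = 9.03e-19), and 3' UTR peaks 11.3% and 0.767% (odds ratio 14.2, adjusted exact p = 2.75e-13). Over all exons of coding genes the odds ratio was 16.7. On autosomes and X outside the rDNA block it was lower, 3.46 (1.65 to 7.24; Fisher's exact p = 5.08e-04). Intron shares were 4.03% and 0.256% (adjusted exact p = 5.70e-05). The 5' UTR shares were 2.47% and 0.512% (adjusted exact p = 0.0290), a call lost with peaks merged (odds ratio 3.55, adjusted exact p = 0.0601) and without rDNA (2.91, adjusted exact p = 0.137). Peaks antisense to a gene were 4.03% and 0.767% (adjusted exact p = 0.00198), a call lost at 30 nt or more (odds ratio 2.94, adjusted exact p = 0.0768). In the other direction, scaffolds without annotation held 15.7% and 43.7% (adjusted exact p = 5.00e-28) and rRNA exons 18.1% and 29.9% (adjusted exact p = 4.80e-06). Without rDNA the few remaining rRNA peaks gave an odds ratio of 1.82 in place of 0.519 (adjusted exact p = 0.577). Intergenic peaks were 10.3% and 15.9% (odds ratio 0.608, adjusted exact p = 0.00757), but without rDNA the order reversed, with 51 of 1068 peaks in chromatin and 1 of 213 in nucleoplasm (odds ratio 7.17, adjusted exact p = 0.00638). Transposable elements held 69 chromatin peaks (4.87%) and 0 of 391 in nucleoplasm, where the interval reaches 0.973% (adjusted exact p = 2.56e-07). Small non-coding RNA exons held 13.1% and 6.91% (adjusted exact p = 0.00175), a call lost without rDNA (odds ratio 1.43, adjusted exact p = 0.180). As target genes, rRNA genes were 32 of 634 in chromatin and 19 of 56 in nucleoplasm (adjusted exact p = 3.64e-08; 2.56e-09 adjusted over the list alone). Spliceosomal snRNA genes were 2.84% and 12.5% (odds ratio 0.198, adjusted exact p = 0.0276; 0.00967 adjusted over the list alone). This call was lost with copies counted once (adjusted exact p = 0.0728), at 30 nt or more (adjusted exact p = 0.0598) and with protein-coding genes left out (adjusted exact p = 0.501). The odds ratio kept its direction in each. Transfer RNA genes, 17.8% and 26.8%, did not differ by the test (adjusted exact p = 0.762) but did with copies counted once (odds ratio 0.204, adjusted exact p = 0.0223) and without rDNA (0.323, adjusted exact p = 0.0288), while with protein-coding genes left out the odds ratio was 2.23 (adjusted exact p = 0.100).

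Within Kc cells the fractions differed in small RNAs, transposable elements and CDS. Small non-coding RNA exons held 11% of chromatin and 6.23% of nucleoplasm peaks (adjusted exact p = 0.00704). The snoRNA genes were 41 of 197 target genes in chromatin and 8 of 123 in nucleoplasm (odds ratio 3.60, adjusted exact p = 0.00574; 8.05e-04 adjusted over the list alone). Transposable elements held 3.09% and 0.916% (adjusted exact p = 0.0207). CDS peaks were fewer in chromatin, 2.06% against 4.40% (odds ratio 0.461, adjusted exact p = 0.0301), but the call was lost among peaks of at least 30 nt (odds ratio 0.829, adjusted exact p = 0.831) and by class over the whole peak (adjusted exact p = 0.0569). Over all exons of coding genes the odds ratio was 0.340 (Fisher's exact p = 3.54e-05) on autosomes and X outside the rDNA block. At 40 nt or more it was 1.61 (Fisher's exact p = 0.208). Exons of rRNA, 32.4% and 34.2%, did not differ by the test (adjusted exact p = 0.579), but did with peaks within 50 nt merged (odds ratio 0.570, adjusted exact p = 0.00119). Scaffolds without annotation, 27.7% and 32.4%, did not differ by the test (adjusted exact p = 0.104), but did without rDNA (odds ratio 0.625, adjusted exact p = 0.00708). No other gene list differed by the test, with an adjusted exact p of 0.911 for sex determination (0 and 2) and of 1 for the others, including rRNA genes (33 and 26), tRNAs (36 and 21) and snRNAs (7 and 4).

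Target genes were shared between lists more often than random gene sets would be, mostly through rRNA and small RNA genes. S2 and Kc chromatin shared 95 genes against 6.80 for independent lists (adjusted exact p = 3.04e-85), of which 19 were protein-coding against 2.15 (adjusted exact p = 1.19e-12). S2 and Kc nucleoplasm shared 27 genes and 0 protein-coding ones. The chromatin and nucleoplasm lists shared 47 genes in S2, 4 of them protein-coding, and 45 in Kc, 6 of them protein-coding. With copies counted once, the 95, 27, 47 and 45 shared genes fell to 58, 10, 21 and 27, and without rDNA and rRNA genes to 62, 8, 28 and 18. The 19 protein-coding genes included Act5C, pAbp, sqd, ps and kst, and in 3 of them, CG1909, larp and pAbp, an S2 peak overlapped a Kc peak. CG1909 and larp were named after their values were seen. With all annotated genes as background, these excesses also contain the genes that both lines express.

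Within shared genes, peaks coincided slightly more than random placement gave. Of S2 chromatin peaks in genes shared with Kc chromatin, 73.7% overlapped a Kc peak against 65.7% for random placement (SD 1.98), with a permutation p of 0.0010, the smallest possible. For Kc chromatin on Kc nucleoplasm the shares were 58.8% and 51.8% (SD 2.44; permutation p = 0.0020). Without rDNA and rRNA genes the last share was 56% (permutation p = 0.0549). For S2 on Kc nucleoplasm and for S2 chromatin on S2 nucleoplasm the permutation p was 0.0629, with shares of 62.4% and 45.3%. These calls changed with the setting: S2 on Kc nucleoplasm passed under 2 alternatives and S2 chromatin on S2 nucleoplasm under 6 (1 of them resting on 1 of 4 peaks), with 80.6% without rDNA and rRNA genes (permutation p = 0.00599). In longer genes other than rRNA, 3 of 35 S2 chromatin peaks overlapped a Kc chromatin peak, 8.57% against 1.54% by random placement (permutation p = 0.0140).

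Ribosomal RNA genes had the most peaks of any gene in all 4 larger lists. The 28S copy 28SrRNA:CR45844 on the rDNA scaffold (70955 to 74924) had 18 peaks in S2 chromatin, 26 in Kc chromatin, 30 in S2 nucleoplasm and 18 in Kc nucleoplasm. With peaks within 50 nt merged, it had 7, 7, 9 and 10. The 18S copy 18SrRNA:CR41548 (43484 to 45478) had 16, 18, 4 and 10, with 7 and 3 in the chromatin lists after merging. The Kc cytoplasm list of 8 peaks held 5 in rRNA exons, including 18SrRNA:CR41548 and 18SrRNA:CR45838, and 1 in tRNA:Asn-GTT-1-6 at 2R 6162540 to 6162594. That list was too small to test.

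**Figure D3:**
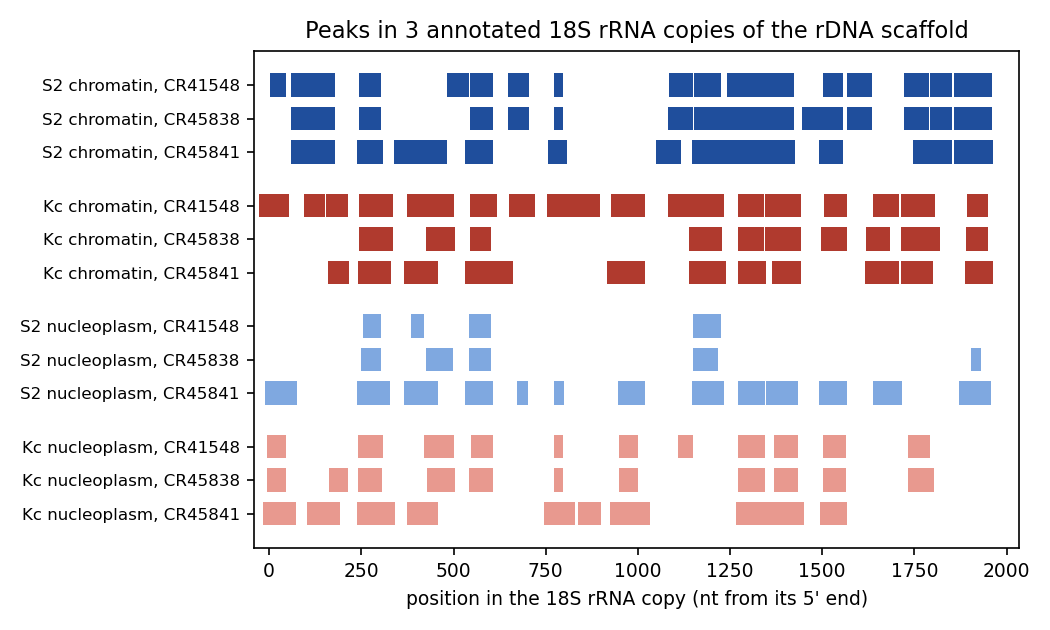
Peaks (bars) of 4 lists in 3 annotated 18S copies of the rDNA scaffold, by position from the 5' end of the copy (x axis, nt). Bars recur at similar positions in several copies, and the 3 copies hold 43 S2 chromatin, 41 Kc chromatin, 22 S2 nucleoplasm and 32 Kc nucleoplasm peaks.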

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

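The tests on rDNA dilution, peak width, shared coding targets and 18S offsets, and the exact form of the test between lines, were chosen after the results were seen.

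The step from nucleoplasm to chromatin differed between S2 and Kc in 8 of 11 classes, by Zelen's exact test of equal odds ratios. The class shares of a list are tied, since a gain in a class lowers the shares of others. The 8 calls are therefore not separate differences. The ratio of the S2 odds ratio to the Kc odds ratio was 34.5 for CDS (11.2 to 106; adjusted exact p = 2.02e-12), 13.1 for 3' UTRs (adjusted exact p = 9.26e-06), 16.8 for 5' UTRs (adjusted exact p = 0.00541) and 7.94 for introns (adjusted exact p = 0.0109). For transposable elements it was 12.6 (0.673 to 237), and the call rested on the exact test (adjusted exact p = 0.0374), since the normal approximation run first gave an adjusted p of 0.124. It was below 1 for rRNA exons (0.565, adjusted exact p = 0.00301), intergenic peaks (0.588, adjusted exact p = 0.0338) and scaffolds without annotation (0.300, adjusted exact p = 1.81e-11). Calls for CDS, 3' UTRs and scaffolds were kept under all 5 alternatives, while the others were lost under at least 1, and without rDNA the ratio was 2.03 for intergenic peaks, in the opposite direction (adjusted exact p = 0.721), and 0.872 for rRNA exons (adjusted exact p = 1). Over all exons of coding genes the ratio was 26.4 (12.2 to 57.4). It was 10.2 (4.17 to 24.9; exact p = 1.02e-07) on autosomes and X outside the rDNA block. Among peaks of at least 40 nt it was 26.7 (4.48 to 159; exact p = 1.06e-05), which rests on 1 coding exon peak of 303 in S2 nucleoplasm. At that width the Kc odds ratio of chromatin over nucleoplasm was 1.61, in place of 0.632 over all peaks.

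Peaks in exons of coding genes made up 29.3% of S2 chromatin and 5.49% of Kc chromatin peaks, an odds ratio of 7.07 (5.18 to 9.65). Dilution of the Kc list by rRNA and scaffold peaks is argued against as the whole cause, since outside rDNA and scaffolds the odds ratio was 3.67 (2.59 to 5.20; Fisher's exact p = 6.03e-15), though the lower value leaves room for a part. Short S2 peaks are argued against as the whole cause too, with an odds ratio of 6.0 (3.84 to 9.40; Fisher's exact p = 2.18e-19) at 40 nt or more. Of 415 S2 coding exon peaks, 122 were that wide, and of 48 in Kc, 24 were. The shares at that width were 17.6% in S2 and 3.38% in Kc, so a part played by short peaks is left open. Deeper sampling of the same coding targets stays open, because 26.4% (17.6 to 37.6%) of Kc chromatin coding targets were in the S2 list, while within lines 10.2% of Kc nucleoplasm coding targets were in Kc chromatin and 40% (4 of 10; 16.8 to 68.7%) of S2 nucleoplasm coding targets in S2 chromatin, too few and too uneven for a yardstick. The sex of the lines, their expression levels and background without antibody were not tested.

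Scaffolds without annotation held 222 peaks in S2 chromatin, 242 in Kc chromatin, 171 in S2 nucleoplasm and 177 in Kc nucleoplasm, outside every gene-level comparison. The Kc cytoplasm list, with 8 peaks, entered no test.

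The many rRNA peaks may in part be single sites called in several near-identical copies. In 3 copies of 18S rRNA, 47.1% of 138 peaks had a peak with both ends within 5 nt of the same offset in another copy, against 2.03% under random placement (permutation p = 0.0010, the smallest possible). The share was 69.8% in S2 chromatin, 36.6% in Kc chromatin, 18.2% in S2 nucleoplasm and 50% in Kc nucleoplasm. Taken over the copies, peaks covered 70.03% of the 1995 nt unit in S2 chromatin, 76.1% in Kc chromatin, 49.4% in S2 nucleoplasm and 55.4% in Kc nucleoplasm. No biological explanation was tested for this pattern.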

How the results depend on the processing

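The settings that left out rDNA, counted copies once, left out genes under 500 nt, left out protein-coding genes or required 30 nt were chosen after seeing the data. Class and gene-list odds ratios were added to the recomputed values after the main results were seen, and those of classes other than CDS, 3' UTRs, rRNA and small RNAs, of rRNA genes and, in chromatin, of tRNA and ribosomal protein genes after alternative values were seen, as were the ratios of S2 to Kc in the step from nucleoplasm to chromatin. Of 480 values recomputed for comparisons, 393 kept their call, and their direction where called, or stayed within their limits, 37 moved, 18 passed the threshold newly, 27 lost it and 5 reversed. Of 716 peak counts of named genes, 658 stayed within counting error and 58 moved. With peaks within 50 nt merged, peaks numbered 527 in Kc chromatin and 353 in Kc nucleoplasm, the 3' UTR odds ratio of S2 against Kc nucleoplasm was 0.265 (exact p = 0.0352), the 5' UTR odds ratio of S2 chromatin against nucleoplasm 3.55 (p = 0.0601), the rRNA odds ratio of Kc chromatin against nucleoplasm 0.570 (p = 0.00119), and 66.9% of S2 chromatin peaks in shared genes overlapped S2 nucleoplasm peaks (permutation p = 0.0010). That overlap was 46.4% with strand ignored (permutation p = 0.0110), 45.3% with placement anywhere (p = 0.0240), 40.7% with 50% of the shorter peak required (p = 0.0010) and 25%, or 1 of 4 peaks, without rRNA genes and genes under 500 nt (p = 0.0410). For S2 on Kc nucleoplasm it was 62.4% with placement anywhere (permutation p = 0.0380) and 60% with 50% required (p = 0.0010). With strand ignored, the intron odds ratio of S2 against Kc chromatin was 1.70 (exact p = 0.0313). By class over the whole peak, the CDS odds ratio of Kc chromatin against nucleoplasm was 0.515 (exact p = 0.0569). Counted as peaks, the X odds ratio in chromatin was 0.420 (exact p = 1.73e-09), from peaks of the X rDNA block. Shared numbers fell by construction with protein-coding genes alone and with copies counted once. In the order S2 and Kc chromatin, S2 chromatin and S2 nucleoplasm, S2 chromatin and Kc nucleoplasm, Kc chromatin and S2 nucleoplasm, Kc chromatin and Kc nucleoplasm, S2 and Kc nucleoplasm, they were 19, 4, 11, 0, 6 and 0 for coding genes, 58, 21, 33, 14, 27 and 10 for copies counted once, 62, 28, 36, 11, 18 and 8 without rDNA, and 496, 266, 343, 317, 401 and 239 as positions. With coding genes alone, 0 gene lists differed in S2 against Kc chromatin, in S2 chromatin against nucleoplasm and in Kc chromatin against nucleoplasm. Without rDNA, 481 peaks remained in Kc chromatin, 213 in S2 nucleoplasm, 286 in Kc nucleoplasm and 2 in Kc cytoplasm, and 1 list, the snoRNAs, differed between the chromatin lists, since rRNA genes were left out. With copies counted once it was also the snoRNAs alone (1 list), as the rRNA gene odds ratio was 0.274 (exact p = 0.236). Without rDNA the rRNA odds ratio was 0.647 for S2 against Kc chromatin (exact p = 0.332) and reversed to 1.82 for S2 chromatin against nucleoplasm (p = 0.577), since few rRNA peaks remained. The small RNA odds ratio of S2 chromatin against nucleoplasm was then 1.43 (exact p = 0.180), its 5' UTR odds ratio 2.91 (p = 0.137), the scaffold odds ratio of Kc chromatin against nucleoplasm 0.625 (p = 0.00708), the 3' UTR odds ratio of S2 against Kc nucleoplasm 0.273 (p = 0.0397), the tRNA odds ratio of S2 chromatin against nucleoplasm 0.323 (p = 0.0288), and the overlaps 56% for Kc chromatin on nucleoplasm (permutation p = 0.0549) and 80.6% for S2 chromatin on nucleoplasm (p = 0.00599). With copies counted once, odds ratios for S2 chromatin against nucleoplasm were 0.0816 for snRNAs (exact p = 0.0728) and 0.204 for tRNAs (p = 0.0223). Antisense odds ratios lost the call for S2 against Kc chromatin with peaks merged (1.52, exact p = 0.219), by class over the whole peak (1.76, p = 0.0569) and at 30 nt or more (1.92, p = 0.0949), and for S2 chromatin against nucleoplasm at 30 nt or more (2.94, p = 0.0768). Without rDNA the intergenic odds ratio reversed to 1.63 for S2 against Kc chromatin (exact p = 0.177) and to 7.17 for S2 chromatin against nucleoplasm (p = 0.00638), since most intergenic peaks lay in rDNA. The S2 to Kc ratio of the step was then 0.872 for rRNA (exact p = 1), 9.59 for transposable elements (p = 0.102), 6.06 for introns (p = 0.0567) and, reversed, 2.03 for intergenic peaks (p = 0.721). For transposable elements it was 10.2 with peaks merged (exact p = 0.0834). At 30 nt or more it was 0.720 for rRNA, 8.82 for 5' UTRs, 9.72 for transposable elements, 9.76 for introns and 0.657 for intergenic peaks (exact p = 0.157 for each). With protein-coding genes left out, odds ratios for S2 against Kc chromatin were 0.486 for rRNA genes (exact p = 0.0549) and, reversed, 2.69 for tRNAs (p = 7.02e-04), and 0.491 for snRNAs of S2 chromatin against nucleoplasm (p = 0.501), which left 1 list differing there. These shares rise by construction where coding targets were many. At 30 nt or more the snRNA odds ratio was 0.165 (exact p = 0.0598), which left 1 list differing between the S2 fractions. At that width the CDS odds ratio was 0.273 for S2 against Kc nucleoplasm (exact p = 0.0949) and 0.829 for Kc chromatin against nucleoplasm (p = 0.831), the intron odds ratio of S2 against Kc nucleoplasm 0.106 (p = 0.0832), the 3' UTR odds ratio of S2 against Kc nucleoplasm 0.0543 (p = 0.00594), and the small RNA odds ratio of S2 against Kc chromatin 1.54 (p = 0.00636). Where no construction is named, the cause was not tested. Class and list p-values are adjusted Fisher's exact values, those of the step adjusted Zelen's exact values, and overlap p-values come from permutation. No paired analysis was possible because the replicate numbers in the labels belong to libraries, and each line and fraction has 1 list with no values per replicate. For the same reason no replicate could be left out. A stricter score threshold was not run because every score was 0, nor were sequence tests, because no genome sequence was used here. Depth is unknown and limits the reading of every count of 0.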

Other observations

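The tests on transposable element families and on the division of snoRNAs by box were chosen after the counts were seen.

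Among transposable element peaks, 69 in S2 and 27 in Kc chromatin, the family 297 had 18 in S2 and 0 in Kc (adjusted exact p = 0.00860, over the 7 families with at least 3 peaks in a list), and jockey 0 in S2 and 3 in Kc (adjusted exact p = 0.0478). Elements of copia had similar numbers of peaks, 18 in S2 and 21 in Kc, so their lower share in S2 (26.1% against 77.8%, adjusted exact p = 3.92e-05) came with the peaks of other families there. For diver (7 and 0) the adjusted exact p was 0.324, and for roo (4 and 0), blood and 3S18 (3 and 0 each) it was 0.574. Copy numbers in the lines were not known, and the tests counted peaks in different copies of an element as independent.

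Mitochondrial transcripts appeared in chromatin and nucleoplasm lists of both lines. In S2 chromatin, 18 peaks lay in the rRNAs mt:lrRNA and mt:srRNA, 14 in tRNAs and 10 in mRNAs such as mt:ATPase6 (3 peaks), and in Kc chromatin 11, 8 and 0. The numbers were 2, 0 and 0 in S2 nucleoplasm and 4, 4 and 0 in Kc nucleoplasm. The Y chromosome and its unplaced sequences carried 9 peaks in the S2 chromatin list and 3 in the list of the female Kc line. A position was shared, Y 3302990 to 3303025 in S2 and Y 3302970 to 3303025 in Kc. Peaks on Y sequence in a female line need not come from a Y chromosome, so no contrast between the lines is drawn from these counts. The origin of these reads was not tested.

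Among snoRNA genes whose names give their box class, H/ACA RNAs were 22 of 36 in Kc chromatin and 6 of 24 in S2 chromatin, an odds ratio of 4.42 (1.45 to 13.4; Fisher's exact p = 0.00839). With genes within 10 kb counted once it was 2.84 (0.830 to 9.71; Fisher's exact p = 0.124), and with peaks of at least 40 nt 1.64 (0.321 to 8.35; Fisher's exact p = 0.678). Both values met the bound set beforehand for clusters of snoRNA genes, and for wider Kc peaks on the longer H/ACA RNAs (median 140 nt against 79 nt), as the cause. They rest on 43 clusters and 24 genes and their intervals include 4.42, so, in a reading adopted after the values were seen, both explanations were left open. The pattern may therefore be technical, and a difference between the lines was not tested apart from these.

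A hypothesis that S2 chromatin peaks in coding exons lie near splice junctions was not borne out. Of 405 peaks, 11.1% were within 50 nt of a junction, against 14.6% for random placement over all exons of the same genes (permutation p = 0.0300; adjusted p = 0.0599). The peaks did lie in 3' UTRs more often than UTR length gives, 39.8% against 28.1% (two-sided permutation p = 0.0020, the smallest this two-sided test can give; adjusted p = 0.00799). They lay in CDS less often than random placement gave, 51.6% against 57.5% (permutation p = 0.00999, adjusted p = 0.0300). The same held for 5' UTRs, 8.64% against 14.3% (permutation p = 0.0020, adjusted p = 0.00799). These shares are tied to the 3' UTR share. In Kc chromatin the 3' UTR shares were 58.3% and 36.9% (28 of 48 peaks; permutation p = 0.0020), and in Kc nucleoplasm 37.8% and 40.3% (permutation p = 0.797). Random placement used exons of every annotated isoform, so isoforms not expressed in these cells could shift the comparison.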
